A study of Bemisia tabaci with 9 samples.

How the data were processed

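Total RNA of Bemisia tabaci biotypes B and Q, kept at 40 C or 25 C for 3 h, was extracted with Trizol and labelled by the aminoallyl method, per the labels' protocols, and hybridised on 9 two-colour arrays. Every array had 1 dye orientation within its comparison: Cy5 held the 40 C sample on the 6 heat arrays and B on the 3 arrays of B against Q, per the labels. No dye was swapped, so a bias of a clone towards a dye adds to each of the first 3 comparisons and cancels only in the difference between the heat responses. The groups were taken from the titles. On slide 8 the biotype tag of the Cy3 channel names B, against the title and the source name, and the title was followed.

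The scanner tables hold the intensity of each spot and of its local background in both channels, with no background subtracted, per the file headers. The scanner software and its version are not given in the sources used here. The brightest spots of a channel piled up at 1 ceiling per channel and array, between 53745 and 79182 intensity units, so both channels appear to have been rescaled after scanning. Between 4 and 333 spots per channel and array lay within 1 unit of that ceiling, and they were kept. The deposited value table holds log2 ratios of Cy5 over Cy3, uncentred: it matched the log2 of the ratio-of-medians column of the scanner tables to within 4.99e-05. The medians of its columns were 0.02, 0.02 and -0.06 for slides 1 to 3, 0.09, 0.04 and 0.05 for slides 4 to 6, and -0.29, -0.15 and -0.14 for slides 7 to 9. Its scale, centring and direction were settled by that match, and it was used as an alternative. It entered as it stands, with no centring, no loess and flagged spots kept, and 39 of its values lay beyond 10 in size.

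The intensities were background-corrected with normexp (offset 50) and normalized by global loess within each array in limma 3.58.1 under R 4.3.3. Flagged spots had weight 0 and were left out (282 to 518 of 5772 per array). The 17 wells with 2 spots, which include the named genes, were averaged. A clone was tested where at least 2 arrays of each group compared had an unflagged value, a limit set after the design. CYP6-like protein 3 was flagged on all 9 arrays and has no value. All 9 arrays entered a fit of group means with 6 residual degrees of freedom. Each group mean, and the difference of the heat groups, was tested two-sided with limma's moderated test, with Benjamini-Hochberg adjustment over all clones tested and a threshold of 0.05. No replicate number is shared between groups.

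On simulated arrays with 200 changed clones and the measured spread of each clone, limma recovered 93% of changes of 1 log2 in Q, 94% in B, 92% in B against Q and 76% in the difference between B and Q. For changes of 0.5 log2 it recovered 51%, 57%, 60% and 20%. Unchanged clones made up 12.2% of the calls in Q, 16.6% in B, 35.6% in B against Q and 5.88% in the difference. These shares depend on the number of changed clones, here 200, where B against Q had 2696 calls in the data. They are therefore not the error rates of the counts given below. With the spreads moderated within each group the shares of unchanged clones were 3.26%, 0.565%, 22.6% and 1.53%. In B against Q they were 5.36% and 2.11%, with measured and moderated spreads, when the 3 arrays were fitted alone. In such fits heat in Q had 6.16% and 6.76%, heat in B 3.61% and 5.5%, and the difference 9.16% and 3.87%. The steps ran on 5285, 5433, 5465 and 5276 clones. The fit that shares the spread therefore understates the error of B against Q with either spread. It does so for heat in Q and heat in B with the measured spreads only.

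Before the data were examined, 18 gene lists were fixed (heat shock proteins and chaperones, ubiquitin and proteasome, antioxidants, detoxification, ribosomal proteins, translation factors, respiration, glycolysis, sugars and polyols, cytoskeleton, muscle, egg and ovary, cuticle, digestive proteases, symbionts, viruses, neuronal genes and transposable elements). They were matched to the names in the files. Of these, 16 lists had no member, since the files pair nearly all clones with no gene name, and the reference table of genes (assembly PGI_BMITA_v3) matched none of the clone names. Heat shock genes were therefore not analysed here, nor the marker lists of tissues, symbionts and viruses. The neuronal list had 2 members (AChE1 and Ache2), which were only described. The detoxification list had 11 members, 10 of them measured, and was tested with camera at a preset correlation of 0.01, adjusted over the 4 comparisons.

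The rule for named genes was fixed at the same time: the 12 highest and 12 lowest named genes past the threshold in each comparison, up to 4 members per list, and at most 2 unnamed clones higher and 2 lower. As the files name so few genes, values of named genes that missed the threshold are given too, a choice made after the data were seen. The unnamed clones printed are the extremes among called clones that were unflagged and above background (2 background SDs in both channels) on every array compared, a limit added after the design. Alternatives fixed before the data were examined were no background correction, plain subtraction, loess within blocks (of at least 50 spots), median centring, scaling between arrays, Aquantile, a filter on dim spots, flagged spots kept, each comparison's arrays fitted alone, eBayes with trend and robust, a limit of 2-fold, the deposited value table, calls shared in direction with B against Q left out, and leaving out each array. Chosen after the data were seen were leaving out spots at the ceiling, array weights, mean centring, a detoxification list with COE1, COE2 and YPCM1vQ added, and the groups of clones by name prefix. Median and mean centring were used in place of loess.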

Results

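RNA of the whitefly Bemisia tabaci, a sap-feeding insect pest of crops, was compared on 9 two-colour arrays, 3 for each of 3 comparisons. The insects belonged to biotypes B and Q, forms of the species that look alike, and were kept for 3 h at 40 C or at 25 C. Slides 1, 2 and 3 set Q at 40 C against Q at 25 C, slides 4, 5 and 6 set B at 40 C against B at 25 C, and slides 7, 8 and 9 set B against Q, both at 25 C. The series title names thermotolerance of the biotypes as its subject. Each array carried 5772 spots from 5755 wells of source plates, of which 16 had a gene name and 5738 only a clone name. One further well was named Mo1, with no statement of what it is. The 16 named genes were 5 CYP4-like and 5 CYP6-like cytochromes P450, the P450s CYP6CM1vB and YPCM1vQ (as the files spell it), the esterases COE1 and COE2, and the acetylcholinesterases AChE1 and Ache2. The names CYP6CM1vB and YPCM1vQ both hold CM1, and the files do not say whether they are 1 gene or 2. P450s and carboxylesterases break down foreign compounds, insecticides among them, and acetylcholinesterase ends signalling at synapses that use acetylcholine. Clones can share a transcript, so the totals below count clones and not genes. All named genes came from neighbouring wells of 1 source plate. Their 2 spots differed together on some arrays. On slide 7 the log2 ratio of the first spot minus the second lay below 0 for every measured named gene but CYP6-like protein 5 (0.06), down to -1.74 for Ache2. On slide 4 it lay above 0 for all but COE1, CYP4-like protein 2 and CYP6-like protein 5, and on slide 8 the signs were mixed. Whether an offset of that area also moved the averaged ratios away from those of other clones was not tested. Between 91.2% (slide 3) and 97.3% (slide 1) of spots lay above background in both channels, and 282 (slide 7) to 518 (slide 3) spots carried a scanner flag. The labels do not say that the 3 slides of a comparison came from separate cultures, so the p-values measure the spread between slides, which may be technical, and the number of arrays limits the precision.

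The first comparison asked which transcripts differed after 3 h at 40 C in Q. No named gene passed the test, and 12 of the 15 measured named genes had a mean log2 ratio below 0. CYP4-like protein 4 had the lowest, with a log2 ratio of -0.30 ± 0.08 (SD, n = 3; adjusted p = 0.131, limma), and lay below 0 on all 3 arrays. The highest was Ache2 at 0.15 ± 0.12 (SD, n = 3; adjusted p = 0.803). The esterases lay at -0.11 ± 0.22 for COE1 and -0.08 ± 0.25 for COE2 (SD, n = 3), and CYP6CM1vB at -0.08 ± 0.12. Among the 10 measured P450s of the detoxification list, 0 passed, 8 lay below 0, and 0 passed when adjusted over the list alone. Among all 15 named genes 1 had an unadjusted p under 0.05 with limma. CYP4-like protein 4 did pass with scaled arrays (adjusted p = 0.0148), with the 3 arrays fitted alone (adjusted p = 0.0456) and with array weights (adjusted p = 0.000200), and its adjusted p ranged up to 0.488 over the alternatives. Array weights put 6 more named genes past the threshold, all lower: COE1, CYP6CM1vB, CYP4-like proteins 2 and 3 and CYP6-like proteins 1 and 4. Without slide 2 only 7 of the 15 lay below 0. The list median was -0.06 against 0.01 for the other clones, which camera did not separate (adjusted p = 0.276). The median was 0.02 without slide 2 and -0.15 without slide 3.

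Among the clones, 513 of 5285 tested passed an adjusted p of 0.05 after heat in Q, 323 higher and 190 lower, with a median size of 0.53 log2. The clone HBT008_F09_T3_078 was higher at 40 C by a log2 ratio of 1.39 ± 0.03 (SD, n = 3; 2.62-fold, adjusted p = 3.36e-05). BT-H-016-1-G10-T3_G10 was higher by 1.44 ± 0.91 (adjusted p = 0.00526), with 0.62, 1.27 and 2.42 on slides 1 to 3, and it missed the threshold with the 3 arrays fitted alone (adjusted p = 0.0532). BT-TYLCV-045-1-F3-T3_F03 was lower, at -0.91 ± 0.48 (adjusted p = 0.00543), as was BT-TYLCV-030-1-H10-T3_H10, at -0.84 ± 0.15 (adjusted p = 0.00739). The first of these missed the threshold without slide 2 (adjusted p = 0.0620) and the other without slide 3 (adjusted p = 0.0780). HBT008_F09_T3_078 and BT-TYLCV-045-1-F3-T3_F03 also differed in the same direction between B and Q at 25 C, by 0.64 and -0.44. A bias of a clone towards a dye would move heat in B too, where HBT008_F09_T3_078 lay at -0.00 (adjusted p = 0.993) and BT-TYLCV-045-1-F3-T3_F03 at -0.61 (adjusted p = 0.0463). The count fell to 316 without slide 1, 38 without slide 2 and 28 without slide 3, and was 1441 with the arrays scaled to a common spread and 2386 with array weights. Of the calls 63.0% were higher after loess, against 45.4% after median centring, 45.3% after mean centring and 42.7% in the deposited value table, so the balance of higher and lower clones was not settled.

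The second comparison put the same question to B. No named gene passed, and 12 of 15 had a mean log2 ratio below 0. CYP6-like protein 5 had the lowest, at -0.60 ± 0.16 (SD, n = 3; adjusted p = 0.0722, limma), and lay below 0 on all 3 arrays. Adjusted over the named genes alone its p was 0.0415. COE2 lay at -0.53 ± 0.44 (adjusted p = 0.126) with one slide near 0, AChE1 at -0.37 ± 0.26 (adjusted p = 0.404) and COE1 at -0.32 ± 0.21 (adjusted p = 0.232). CYP4-like protein 2 was the highest, at 0.07 ± 0.24, with all its spots above background on only 1 of the 3 arrays. Over the alternatives it ranged from -0.59 to 0.21. Of the 10 measured P450s of the detoxification list 0 passed, 7 lay below 0, and 1 passed when adjusted over the list alone, CYP6-like protein 5. The list median was -0.09 against -0.00056 for the other clones, and camera did not separate it (adjusted p = 0.162). The median was -0.05 without slide 4 and -0.16 without slide 6. The unadjusted p was under 0.05 for 4 of the 15 named genes with limma. CYP6-like protein 5 did pass with scaled arrays (adjusted p = 0.00821), with array weights (adjusted p = 0.00654), and without slide 7 (adjusted p = 0.0254) or slide 9 (adjusted p = 0.0337), and its adjusted p ranged up to 0.280 over the alternatives. COE2 passed with scaled arrays (adjusted p = 0.0375), and its adjusted p ranged up to 0.424.

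Among the clones, 142 of 5433 tested passed after heat in B, 80 higher and 62 lower, with a median size of 0.56 log2. The clone BT-TYLCV-025-1-F5-T3_F05 was higher at 40 C by 1.42 ± 0.12 (SD, n = 3; 2.68-fold, adjusted p = 0.000177) and BT-H-046-1-B11-T3_B11 by 1.07 ± 0.12 (2.09-fold, adjusted p = 0.000177). BT-TOMOV-026-1-H11-T3_H11 was lower, at -1.41 ± 0.80 (adjusted p = 0.0156), and reached the scanner's ceiling on 1 of the 3 arrays. BT-H-019-1-B4-T3_B04 was lower at -1.10 ± 0.10 (adjusted p = 0.0156). Both missed the threshold without slide 4 (adjusted p = 0.0856 and 0.0885) or slide 5 (adjusted p = 0.123 for each), and BT-H-019-1-B4-T3_B04 also without slide 6 (adjusted p = 0.0831). In the fit of these arrays alone BT-TOMOV-026-1-H11-T3_H11 missed it too (adjusted p = 0.0603), as both did in the deposited value table (adjusted p = 0.0652 and 0.0548). All 4 clones differed in the same direction between B and Q at 25 C, and without clones of that kind 36 of the 142 calls were left. After heat in Q the 4 clones lay at -0.59, 0.28, 0.91 and 1.05, of which only 0.28, for BT-H-046-1-B11-T3_B11, had the sign seen in B. The count was 5 without slide 4, 5 without slide 5 and 24 without slide 6. Through the shared spread it was also 73 without slide 1, 31 without slide 2 and 224 without slide 9. It was 38 with the 3 arrays fitted alone, 93 after median centring, 11 in the deposited value table, 691 with scaled arrays and 1019 with array weights.

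The third comparison set the biotypes side by side at 25 C. Of the named genes 5 of 15 passed, all lower in B than in Q. The number was 11, all lower, without slide 7, 3 without slide 1, 2 or 6, and 3, of which Ache2 was higher, without slide 9. Without slide 8 it was 4, of which CYP4-like protein 5 was higher, at 0.60 (adjusted p = 0.0144). It was 10 of 15 after mean centring and 7 of 16 in the deposited value table, all lower, 5 after median centring, 3 with loess within blocks, and 1 with scaled arrays. Without slide 7 all 15 lay below 0. As the named genes came from neighbouring wells, their common direction may not be independent between genes. CYP4-like protein 4 had a log2 ratio of B over Q of -0.60 ± 0.12 (SD, n = 3; adjusted p = 0.000854, limma), and CYP6CM1vB of -0.43 ± 0.18 (adjusted p = 0.00457). Both lay below 0 on all 3 arrays. YPCM1vQ followed at -0.41 ± 0.39 (adjusted p = 0.0360), COE2 at -0.46 ± 0.45 (adjusted p = 0.0435) and CYP4-like protein 3 at -0.35 ± 0.31 (adjusted p = 0.0449). Leaving out each array, YPCM1vQ ran from -0.62 to -0.24, COE2 from -0.72 to -0.31 and CYP4-like protein 3 from -0.44 to -0.17. Adjusted over the named genes alone, 2 passed, CYP4-like protein 4 and CYP6CM1vB. The acetylcholinesterases spread widely on the 3 slides: Ache2 had log2 ratios of 1.41, -0.09 and -0.42, and AChE1 of 0.63, -0.18 and -1.14 on slides 7 to 9, with means of 0.30 ± 0.98 and -0.23 ± 0.89 (SD, n = 3) that missed the threshold. Leaving out slides 7 to 9 in turn, the mean of Ache2 ran from -0.25 without slide 7 to 0.66 without slide 9 (adjusted p = 0.0464). That of AChE1 ran from -0.66 without slide 7 (adjusted p = 0.0177) to 0.22 without slide 9, so neither direction was settled. AChE1 had a spot that was not above background on each of these arrays, and CYP4-like protein 3, CYP4-like protein 4, CYP6CM1vB and COE2 had such a spot on 1 of the 3. The filter on dim spots left no value for 12 of the 15 named genes, the 5 called ones among them. CYP6-like protein 5, at -0.42 ± 0.53 (SD, n = 3), missed the threshold but passed in 6 of 24 alternatives, that filter among them (adjusted p = 0.0485), with adjusted p from 0.00324 to 0.422 over them all.

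The detoxification list had 3 of its 10 measured P450s lower in B, 0 higher and 7 not past the threshold, with 2 past it when adjusted over the list alone. Its median was -0.33 against -0.03 for the other clones, and camera did not separate it (adjusted p = 0.162; adjusted p = 0.765 with an estimated correlation of 0.436), although without slide 7 it did (median -0.44, adjusted p = 0.0119). Of the 5 called genes, CYP4-like protein 3, COE2 and YPCM1vQ missed the threshold when the 3 arrays were fitted alone (adjusted p = 0.118, 0.0782 and 0.0907). All 3 also missed it with no background correction, with loess within blocks and with scaled arrays. CYP4-like protein 3 further missed it without slide 1, 5, 6 or 9, with plain subtraction and with array weights, in 11 of 23 alternatives in all (adjusted p up to 0.339, without slide 9). COE2 missed it without slide 1, 2, 6, 8 or 9 and with array weights, also in 11 of 23 (adjusted p up to 0.267, without slide 8). YPCM1vQ missed it without slide 2, 8 or 9, with plain subtraction and in the deposited value table, in 10 of 23 (adjusted p up to 0.285, without slide 8). The limit of 2-fold ended these calls and that of CYP6CM1vB, which also missed the threshold with scaled arrays (adjusted p = 0.0862). CYP4-like protein 4 passed in each alternative that gave it a value, except the limit of 2-fold. The 2 spots of a named gene on an array differed by a median of 0.14 (slide 2) to 0.49 (slide 6) log2, which is as wide as several of these ratios. On slide 7 nearly all of these differences went the same way.

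**Figure D1:**
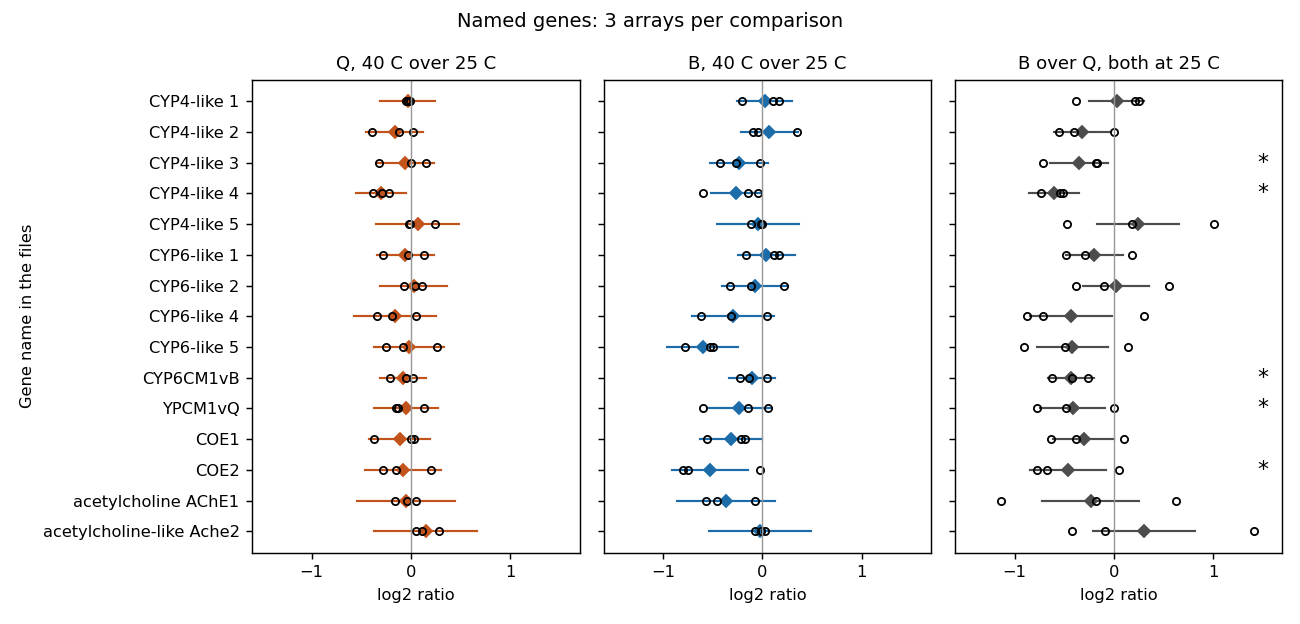
Log2 ratios of the 15 measured named genes in the 3 comparisons; open circles are single arrays (n = 3), diamonds the means, lines the 95% intervals of the limma fit of all 9 arrays, and asterisks mark an adjusted p under 0.05. Asterisks stand only in the comparison of B with Q at 25 C, at 5 genes with means from -0.60 (CYP4-like protein 4) to -0.35 (CYP4-like protein 3).

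Among all clones, 2696 of 5465 tested differed between B and Q at 25 C, 1460 higher in B and 1236 lower. At least 2-fold differences were found for 542 clones, 444 higher in B and 98 lower. BT-TOMOV-031-1-E11-T3_E11 was higher in B by a log2 ratio of 3.76 ± 0.07 (SD, n = 3; 13.5-fold, adjusted p = 9.66e-11) and BT-H-034-1-A5-T3_A05 by 3.74 ± 0.45 (13.4-fold, adjusted p = 3.42e-10). BT-TOMOV-022-1-F11-T3_F11 was lower in B, at -1.81 ± 0.27 (adjusted p = 5.69e-08), and so was BT-TYLCV-014-1-D8-T3_D08, at -1.66 ± 0.39 (adjusted p = 1.20e-06). These 4 clones passed under every alternative tried. The log2 ratios of slides 7, 8 and 9 correlated across clones with r from 0.784 to 0.846, and clones are not independent replicates. Slide 8 carries a tag that names B for the channel its title and source name call Q. Those correlations argue against B in both its channels. So does the SD of its ratios over clones, 0.645, against 0.753 on slide 7, 0.684 on slide 9 and 0.389 on slide 3, the widest heat array. The 3 slides varied more than the heat slides, with a median SD of 0.23 log2 against 0.12 in Q and 0.17 in B, so the shared spread flattered this comparison: with the 3 arrays fitted alone 1937 clones passed. Of the calls 54.2% were higher in B, against 66.0% of 1394 with scaled arrays, 37.6% after mean centring and 36.8% in the deposited value table. That table is uncentred, with medians of -0.29, -0.15 and -0.14 on slides 7 to 9, which moves its calls towards lower.

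The fourth comparison asked whether the response to heat differed between the biotypes, as the ratio at 40 C over 25 C in B minus that in Q. None of the 15 named genes passed (limma; 1 had an unadjusted p under 0.05). CYP6-like protein 5 had the lowest difference, at -0.58 with a 95% interval from -1.08 to -0.08 (adjusted p = 0.134), from -0.60 in B and -0.02 in Q. It passed with the 6 heat arrays fitted alone (adjusted p = 0.0398), with scaled arrays (adjusted p = 0.0300) and with array weights (adjusted p = 0.0460), and its adjusted p ranged from 0.0300 to 0.423 over the alternatives. With array weights CYP4-like protein 2 passed as well, with a higher ratio in B (adjusted p = 0.0108). COE2 differed by -0.45 (95% interval -0.99 to 0.09, adjusted p = 0.298). The widest interval reached 0.73 log2 to either side, so changes of that size in single genes could not be excluded. The detoxification list had a median difference of -0.06 against -0.02 for other clones (camera, adjusted p = 0.794). The median was -0.00 without slide 1, -0.12 without slide 2, -0.02 without slide 3 and -0.03 without slide 4.

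Among the clones, 459 of 5276 tested differed in their heat response, 207 with a higher ratio in B and 252 with a lower one. BT-TYLCV-025-1-F5-T3_F05 had log2 ratios of 1.42 in B and -0.59 in Q, a difference of 2.01 (SE 0.19, adjusted p = 0.000343). BT-HINST-015-1-H6-T3_H06 had 0.96 in B and -0.52 in Q, a difference of 1.48 (SE 0.18, adjusted p = 0.00136). BT-TOMOV-026-1-H11-T3_H11 had -1.41 in B and 0.91 in Q (difference -2.32, SE 0.33, adjusted p = 0.00303), with a spot at the scanner's ceiling on 3 of the 6 arrays. BT-H-019-1-B4-T3_B04 had -1.10 in B and 1.05 in Q (difference -2.14, SE 0.26, adjusted p = 0.00136). These 4 clones passed under every alternative that gave a value. The count was 73 without slide 2, 70 without slide 3, 177 without slide 4, 44 without slide 5 and 271 without slide 6. It was 764 with the 6 heat arrays fitted alone, and 61.7% of 812 calls were higher in B after median centring, 62.0% of 892 after mean centring and 74.3% of 779 in the deposited value table, against 45.1% after loess.

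Clones that changed with heat in one biotype were compared with those that changed in the other and with those that differed at 25 C. Of the 323 clones higher after heat in Q and the 75 higher in B among 5276 tested in both, 5 were shared, against 4.59 for independent lists. The lower lists of 189 and 62 clones shared 1, against 2.22. In opposite directions, 9 clones were higher in Q and lower in B, against 3.80, and 8 were lower in Q and higher in B, against 2.69. All comparisons share 1 spread per clone from the same fit, so clones of small spread are called more easily in each. The counts for independent lists, here and below, are therefore too low a baseline, whichever the directions. Across clones the mean log2 ratios of the 2 heat comparisons had r = -0.171 (rho = -0.155). That r was -0.0129 in the deposited value table and -0.0342 with flagged spots kept, and -0.251 with loess within blocks, -0.261 after median centring and -0.261 after mean centring, so its size was not settled. The direction of every ratio rests on the dyes the labels name. Of the 189 clones lower after heat in Q and tested in both, 146 were higher in B than in Q at 25 C, against 49.8 for independent lists, and 9 were lower, against 43.9. Of the 80 clones higher after heat in B, 61 were higher in B at 25 C, against 21.3, and of the 62 clones lower after heat in B, 45 were lower in B at 25 C, against 14.1. The 323 clones higher after heat in Q were not shifted in this way, with 92 higher in B at 25 C, against 85.1, and 68 lower, against 75.1. To see what shared 25 C RNA would add, 100 simulations of unchanged clones gave it a part of the between-slide variance, drawn anew for each slide. They gave r = 0.182 for Q and -0.217 for B with the 25 C comparison. Measured were -0.140 and 0.274, with ranges from -0.247 to -0.0847 and from 0.205 to 0.405 over the alternatives. RNA common to all 3 slides would not show in that variance, so for it the simulated sizes do not hold. The covariances were -0.0235 and 0.0403, against 0.00357 and -0.00508 simulated. The simulated signs rest on the labelled dyes and would turn with the dyes of the heat arrays.

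**Figure D2:**
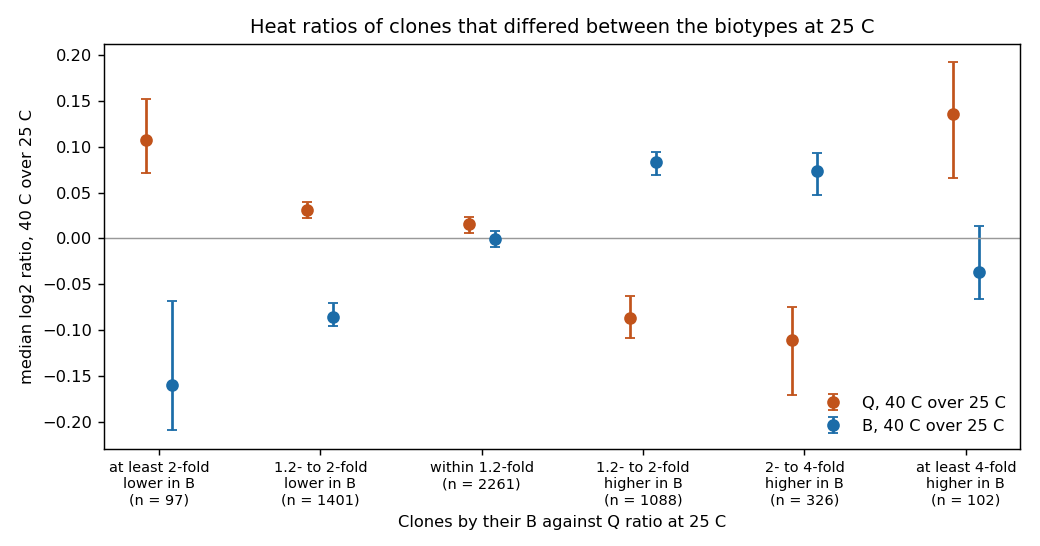
Median log2 ratio of 40 C over 25 C (vertical axis) in Q and B for clones grouped by their B against Q ratio at 25 C (horizontal axis, with the number of clones), with 95% bootstrap intervals over clones. Clones 1.2- to 2-fold higher in B lay at 0.08 in B and -0.09 in Q, and those at least 4-fold higher at -0.04 in B and 0.14 in Q.

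The clone names fall into 7 groups by prefix, and the files do not say what the prefixes stand for. The groups were formed after the data were seen. The 760 HINST clones with values on all arrays stood higher than the other clones in B over Q at 25 C, with a median of 0.21 against -0.06 (camera, adjusted p = 0.00341 over 28 tests; adjusted p = 0.189 with an estimated correlation). They also stood higher after heat in B, at 0.06 against -0.02 (adjusted p = 1.11e-05; adjusted p = 0.148 with an estimated correlation). The size of these shifts was not settled: the HINST median minus that of the other clones was 0.27 in B over Q and ranged from 0.16 with scaled arrays to 0.57 after median centring. After heat in B it was 0.08, against 0.13 without spots at the ceiling and 0.22 after median centring. The 127 HEG clones stood higher after heat in B, at 0.10 against -0.00 (adjusted p = 0.000286; adjusted p = 0.148 with an estimated correlation), and did not pass in B over Q at 25 C (0.10 against -0.04, adjusted p = 0.406). Their shift after heat in B was 0.11, against 0.07 without slide 5 and 0.17 after median centring. In B over Q they passed after median centring (adjusted p = 0.00338), mean centring (adjusted p = 0.00683) and in the deposited value table (adjusted p = 0.00334), and not with an estimated correlation (adjusted p = 0.661). Of the tested HINST clones 43.1% were higher in B and 18.9% lower at 25 C, against 24.0% and 23.2% of the other clones. No group passed after heat in Q, where HINST lay at -0.04 against 0.02 (camera, adjusted p = 0.267, and 0.513 with an estimated correlation). At the preset correlation, median centring (adjusted p = 0.000178), mean centring (adjusted p = 0.000210) and the deposited value table (adjusted p = 7.23e-05) put HINST below the other clones. The HINST shift after heat in Q was -0.05 and ranged from -0.15 to -0.04 over the alternatives.

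**Figure D3:**
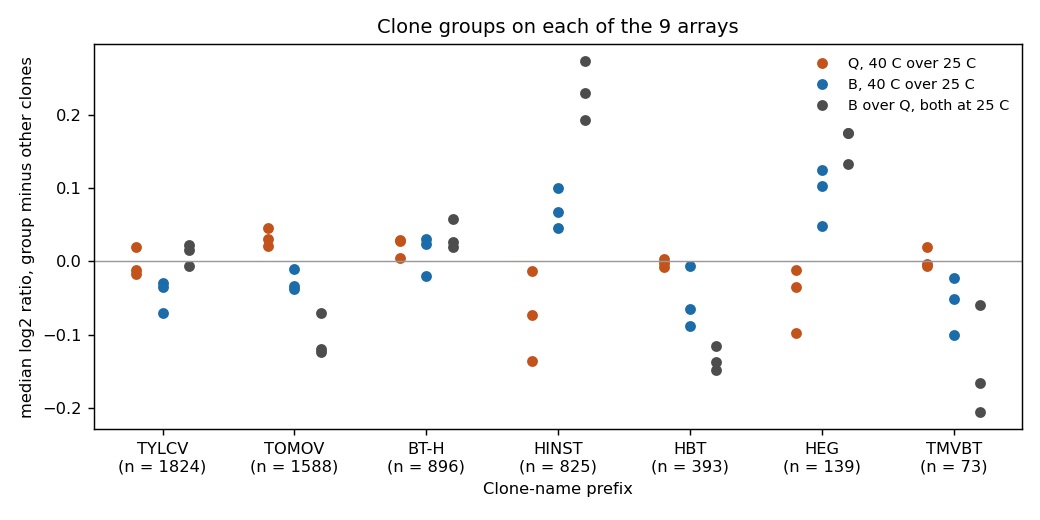
Median log2 ratio of each clone-name group minus that of all other clones (vertical axis) on each of the 9 arrays, 3 per comparison, by prefix and number of clones (horizontal axis). HINST lay from 0.19 to 0.27 above the other clones on the 3 arrays of B over Q at 25 C.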

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

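The tests of source plate for HINST and HEG on their own and the grouping by clone name were chosen after the results were seen; the test of brightness and of both kinds of clone together on plates was written down before its result. The heat response of 459 clones differed between B and Q by the test of the difference itself. The clones printed with it were BT-TYLCV-025-1-F5-T3_F05 with a difference of 2.01 log2, BT-HINST-015-1-H6-T3_H06 with 1.48, BT-TOMOV-026-1-H11-T3_H11 with -2.32 and BT-H-019-1-B4-T3_B04 with -2.14. All 4 had a ratio above 0 in one biotype and below 0 in the other. The 6 heat arrays make only 10 splits into 3 and 3, too few for a share under 0.05; the real split gave 459 clones, 1 split reached that number, and the highest of the others gave 0.

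Relative to other clones, the clones named HINST had a heat response higher in B than in Q by 0.17 log2 (camera, adjusted p = 0.000249; adjusted p = 0.148 with an estimated correlation), and those named HEG by 0.18 (adjusted p = 0.0148; adjusted p = 0.214 with an estimated correlation, and adjusted p = 0.0829 without slide 3). Over the alternatives these differences ranged from 0.12 to 0.38 for HINST and from 0.14 to 0.27 for HEG, highest in the deposited value table. They were flagged because the difference between the biotypes was itself tested.

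The HINST and HEG clones as a joint set were also higher than the other clones in B over Q at 25 C, by 0.25 log2. Loess within each array had already removed the average trend of the ratios with brightness. A comparison within classes of brightness therefore cannot decide whether brightness was the cause. Within 10 such classes the difference was 0.28 (95% bootstrap interval 0.22 to 0.34), past the bounds written down before its result. Within the 3 source plates that hold both kinds of clone it averaged 0.21 (0.11 to 0.28), which argues against plate position by the bounds written down before; it was put down as undecided after the result was seen, because the plates went opposite ways. For HINST alone the difference within 2 plates was 0.36 (0.23 to 0.43), which argues against plate position, while HEG, on 1 plate, had -0.0884 (-0.26 to 0.07), which fits plate position by those bounds but was put down as undecided, also after the result was seen, since its interval passes them. A difference between the biotypes in the transcripts that HINST clones carry may remain as a hypothesis, untested; clones sharing a transcript make these intervals too narrow.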

How the results depend on the processing

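The array weights, mean centring, ceiling filter and longer detoxification list were chosen after the data were seen. Counts of clones past the threshold moved as follows, and the cause was not tested. For heat in Q (513) they were 1441 with scaled arrays, 17 at 2-fold, 2386 with array weights, and 28 to 620 leaving out each array. For heat in B (142) they were 93 after median centring, 691 with scaled arrays, 38 with its arrays alone, 7 at 2-fold, 11 in the deposited value table, 36 without calls shared in direction with B against Q, 1019 with array weights, and 5 to 224 leaving out each array. For B against Q (2696) they were 1394 with scaled arrays and 542 at 2-fold. For the difference of the heat responses (459) they were 774 with loess within blocks, 812 after median centring, 1350 with scaled arrays, 764 with the 6 heat arrays alone, 72 at 2-fold, 779 in the value table, 1798 with array weights, 892 after mean centring, and 44 to 627 leaving out each array. The other count alternatives, 64 in all, stayed within 1.5 times. Aquantile left every count as it was, as it changes brightness and not ratios. The detoxification list in B against Q had medians from -0.44 to -0.17 leaving out each array and passed only without slide 7; its other alternatives did not pass either, although the filter on dim spots left only 2 of its P450s. With COE1, COE2 and YPCM1vQ added, the list passed after heat in B (adjusted p = 0.0415; adjusted p = 0.780 with an estimated correlation), but missed the threshold in 11 of 23 alternatives, without slide 4 among them (median -0.09 in place of -0.23, adjusted p = 0.202). In B against Q the longer list had 5 of 13 members lower and missed the threshold (adjusted p = 0.0552), and it passed in 6 of 23 alternatives, with adjusted p from 0.00161 (without slide 7) to 0.780. After heat in Q the longer list passed only without slide 3 (median -0.15, camera, adjusted p = 0.0401), and its median was 0.02 without slide 2. No named gene, printed clone, gene list or clone group turned its direction while past the threshold. The balance of higher and lower calls did turn under some alternatives in each comparison. Spots above background made up 91.2% or more per array, but the filter on dim spots left no value for 12 of the 15 named genes, including the 5 called in B against Q.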

Other observations

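All tests of the first pattern below were chosen after the result was seen; those of the other pattern were written down before, except that mean centring was added as an alternative later. Each group of 3 arrays allows only 4 sign patterns, too few for a share under 0.05. The real pattern gave 513 clones for heat in Q, 142 for heat in B and 2696 for B against Q, each reached by 1 pattern of the 4, and the highest of the others gave 0 in each.

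Clones lower after heat in Q and clones higher after heat in B were mostly higher in B than in Q at 25 C. A bias of clones towards a dye is argued against as the whole cause, since it would tie all arrays together in the same sense and the highest r between a Q heat array and a B against Q array was -0.0613. Shared control RNA would give the opposite signs with the dyes as labelled. The lowest r between a B heat array and a B against Q array was 0.0322. With the heat dyes turned, shared control RNA would give the signs measured, so this cannot decide while those dyes are in doubt. An unequal response of the dyes to abundance would move the clones at least 4-fold higher in B most. Their median heat ratio in B was -0.0365 (95% bootstrap interval over clones -0.07 to 0.01). That value cannot test such a response, since loess within each array already removed the average trend of the ratios with brightness. Heat arrays with the dyes named the wrong way round cannot be told apart from the pattern: the channel labelled 40 C followed B against Q with r = 0.441, which was 0.141 above the r of the channel labelled 25 C, and that gap correlated at r = 0.905 with the difference of the heat responses itself. A wider gap between the biotypes at 40 C may be the biological explanation and stays open: the SD over clones of B against Q was 0.830 as derived for 40 C against 0.652 at 25 C, which restates the pattern from the same arrays and falls to 0.659 with the heat ratios turned, and as labelled the gap narrowed for clones at least 4-fold higher in B, whose median heat ratio in Q was 0.14, where turned ratios would widen it.

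Most clones at least 2-fold different between B and Q at 25 C were higher in B, 81.9% of 542. On slides 7 to 9 the ceiling was reached by 94, 140 and 100 spots in Cy5 (B), against 7, 4 and 6 in Cy3 (Q). A ceiling in Cy5 lowers B over Q, so it could hardly have raised the share. The share was 80.7% without spots at a ceiling, an outcome that this direction left little room to differ. The share was 90.7% after mean centring and 96.5% after median centring, so neither lowered it. Both settings also left out loess, so they do not test centring alone and cannot decide on it. A wrong biotype for an array set is argued against by the brightness of the heat arrays, whose B minus Q difference followed the B against Q ratio with r = 0.398 across clones and with r from 0.158 to 0.308 over 9 pairs of arrays. It remains open whether the clone sequences came from B, which may favour B RNA, as the origin of the clones is not given in the sources used here, and so does a difference in expression.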
